A study of Mus musculus with 2 samples.

How the data were processed

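The series measured RNA in 2 samples of sorted mouse bone marrow cells with the surface phenotype Lin-c-kit+Sca1+, a population enriched for haematopoietic stem and multipotent progenitor cells. The samples are 1 group, called sample 1 and sample 2 from their titles. The labels name no treatment, second group or contrast. They also do not say whether the samples came from different animals or sorts, so the spread reported here is that between these 2 samples, which may be technical. Per the labels' protocols, the RNA went through 2 rounds of amplification before hybridisation.

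The deposited values were signal intensity values on a linear scale, 1 per probe set, for 12488 probe sets of an Affymetrix mouse expression array in each sample. Which software summarised and scaled them is not given in the sources used here. The deposited intensity columns had means of 53.944 in both samples, as a common scale factor would give. Their medians were 15.9 in sample 1 and 14.45 in sample 2, the lowest values were 0.2 and 0, and the highest were 10368.5 and 8800.7. No detection calls, scanner files or probe-level values were used. On an array the number of samples, here 2, limits the precision.

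The 2% trimmed means, 32.8 and 30.9, differed by 6.15%, above the tolerance of 5% set before the data were examined, so both arrays were quantile-normalized. As 1 deposited value was 0, the fixed rule set signals under 20 to 20 after normalization and before log2. This floor held 57.7% of the values in each sample, so a fold against a sample at the floor is a lower bound and is written "at least". Every signal in the text is a quantile-normalized one. A sample's control level was the 90th percentile of its 15 probe sets for bacterial genes that mice lack (Dap, Lys, Phe, Thr and Trpn). It was 12.1 in sample 1 and 8.91 in sample 2. All 66 control probe sets were left out of the counts.

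Gene names came from the platform's annotation table. Of the 12422 other probe sets, 10833 named 1 gene, 396 named several and 1193 had no name. The named ones covered 8251 genes, and 10817 of the 10833 had a gene ID in the gene table of GRCm38.p6, which changed 0 symbols. Probe sets naming several genes entered no gene. A gene was above the control level if any of its probe sets was above it in both samples. Its value was that of its probe set with the highest mean log2 signal over both samples. No coordinates are printed, because the probe table names no genome build.

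Before the data were examined, 26 gene lists were fixed for stem cells, blood lineages, other tissues and cell functions. For each list the number of measured members above the control level was set beside 10000 random lists of as many named genes. For the 23 lists with at least 5 such members, the median of log2(sample 2) minus log2(sample 1) was set beside 10000 random lists matched on mean signal in 20 bins. A list outside their middle 95% is said to stand apart. Over the 6118 probe sets above the control level the median difference was -0.079 with quantile normalization, -0.18 with the deposited scaling and -0.046 with median-centring. This describes these 2 arrays. With 1 group of 2 samples there is no test of any gene, and no p-value is given. Of 23 lists, chance alone would put about 1.15 apart if genes varied independently of each other. On arrays simulated from the mean signals of the 2 samples (12422 probe sets, noise with an SD of 0.6 on the log2 scale in each array), 9 of 10 lists of 10 genes shifted by 1 stood apart. Of lists shifted by 0.5, 3 of 10 stood apart, and of unshifted lists 5 of 100. The median recovered for a shift of 1 was 0.79. The simulated noise was independent between probe sets, and the simulated lists came only from probe sets with mean signals well above the floor. These rates therefore do not apply to genes that vary together, nor to lists with many genes near the floor.

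The genes named in the text followed a rule set before the data were examined, except in the ranking described below. They are all measured genes of the sorting antigens and lineage antigens, and the 3 members of each other list with the highest mean signal above the control level. To these come the member with the largest difference in each list for mature cells or other tissues, and the 5 genes most different in each direction. For these 5 the fixed rule ranked all probe sets that name 1 gene and were above the control level in both samples. The ranking given here departs from it. It used 1 probe set per gene and only genes with both signals above the floor, since signals at the floor have no order. Genes outside the rule are marked as chosen after their values were seen. The alternatives were 4 other control levels, each sample alone, all probe sets of a gene in place of any, the deposited and the median-centred scaling, an offset of 32 on the log2 scale, no filter, the mean over a gene's probe sets, no floor, and the stem and cyclin lists without their immediate early genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.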

Results

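Gene expression was profiled in Lin-c-kit+Sca1+ cells, the bone marrow fraction that lacks lineage antigens and carries the stem cell factor receptor Kit and the antigen Sca-1. The data are 2 arrays, 1 for each of 2 samples of this fraction, with a signal for 12422 probe sets besides the controls, of which 6118 (49.3%) were above the bacterial control level in both samples. The labels give no second condition. The data therefore address which genes were measured in this population, and how far its 2 samples differed.

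Genes of stem and early progenitor cells were measured in both samples far more often than randomly drawn genes. The counted lineage antigen genes, most of them of T cells, were measured far less often. Of 32 measured stem and early progenitor genes, 28 were above the bacterial control level in both samples, against 13 to 24 in the middle 95% of random lists. Those not above it were Ikzf1, Mecom, Tal1 and Tek. Fli1, Myc and Ptprc counted as above it, though at the floor of 20 in both samples. Where all probe sets of a gene had to pass, the count was 20 of 32. The random lists were not matched on the number of probe sets per gene. Lyl1, a basic helix-loop-helix factor of blood progenitors, had a signal of 695 in sample 1 and 2224 in sample 2 (mean log2 signal 10.28 ± 1.19, SD, n = 2). Its other probe set had 42.7 and 121. Cbfb, the partner of the Runx transcription factors, had signals of 667 and 776 (9.49 ± 0.15, SD, n = 2), and 80.1 and 77.1 by another probe set. Myb, a transcription factor of haematopoietic progenitors, had signals of 490 and 232 (8.40 ± 0.76, SD, n = 2). Kit, on which the cells were sorted, gave only 25.8 and 19.4, above the control levels of 12.1 and 8.91 but next to the floor of 20. Sca-1, encoded by Ly6a, was not analysed here.

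Of 10 measured lineage antigen genes, 2 were above the control level in both samples, against 3 to 9 of random lists. The 2 were Ms4a1, which encodes CD20 of B cells, at 28.3 and 43.5, and the granulocyte antigen gene Ly6g at 14.1 and 9.25. The T cell genes Cd3d, Cd3e, Cd3g, Cd4, Cd8a and Cd8b1 and the myeloid integrin gene Itgam had signals between 1.4 and 9.8, and at least 1 sample of each was not above its control level. Cd5 had 3.0 in sample 1 and 12.0 in sample 2. Ly6c1, also on the lineage antigen list, was not counted, because its probe set also names Ly6c2. That probe set had 1157 in sample 1 and 363 in sample 2. In the wider list of T and NK cell genes, 7 of which the lineage antigen list also holds, 5 of 20 were above the control level, against 7 to 16 of random lists. Among the 5 were Lat, an adaptor of T cell receptor signalling, at 63.6 and 51.9, Thy1 at 14.2 and 42.5, perforin (Prf1) at 16.8 and 32.3, and the kinase gene Zap70 at 29.5 and 15.6. Mast cell, basophil and eosinophil genes were above it in 5 of 18 cases, against 6 to 14, with the mast cell carboxypeptidase gene Cpa3 at 65.4 and 62.8, the tryptase gene Tpsb2 at 34.7 and 81.9, and the protease genes Mcpt8 at 75.2 and 19.0 and Mcpt1 at 13.6 and 32.5. In sample 2 alone, with its lower control level, the counts were 4 of 10 lineage antigens, 13 of 20 T and NK cell genes and 10 of 18 mast cell, basophil and eosinophil genes. Of all 8251 genes, 5860 were above it in that sample.

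Growth and biosynthesis genes were also measured more often than random lists. Of 32 cell cycle genes 29 were above the control level, among them Stmn1, which encodes a microtubule regulator of dividing cells, the replication clamp gene Pcna and the mitotic gene Cdc20. Of 20 ribosomal protein genes 19 were above it, of 30 genes of oxidative phosphorylation 25, and of 16 housekeeping genes 14. Myeloid progenitor and granule genes were above it in 13 of 15 cases, against 5 to 12. Adhesion and homing genes were above it in 18 of 23, at percentile 98.1 of random lists. They included the integrin gene Itgb1 at 3119 and 1755 (120 and 44.4 by another probe set). The gene of the "don't eat me" antigen Cd47 had 1178 and 2667 (63.2 and 41.1 by another probe set). The selectin ligand gene Selplg had 343 and 503.

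The remaining lists differed less from random lists. Of 19 erythroid genes 15 were above the control level (percentile 97.2), and of 31 immediate early and stress genes 23 (percentile 97.7). For B cell genes the count was 9 of 18, for dendritic cell genes 10 of 20, for mature neutrophil genes 9 of 14, for monocyte and macrophage genes 12 of 17, for megakaryocyte genes 4 of 10 and for stromal and endothelial genes 15 of 25. It was 13 of 28 for cytokine receptors, 13 of 30 for Hox genes and 14 of 22 for the Wnt and Notch pathways. It was 15 of 22 for interferon response genes and 8 of 13 for early lymphoid genes. For D-type cyclins, inhibitors of cyclin-dependent kinases and related regulators it was 9 of 17. Among B cell genes the immunoglobulin heavy chain gene Ighm had signals of 935 and 667 by the strongest of its 16 probe sets. Others had 102 and 139, 14 and 9.05, and 14 and 11.9. Of the same list Cd24a had 185 and 181, Jchain 75.9 and 63.9, and the surrogate light chain gene Igll1 19.8 and 30.9 (18.1 and 15.1 by another probe set). Among Hox genes, which encode homeodomain factors, Hoxa4 had 71.5 and 257, Hoxb8 46.3 and 34.0 (15.4 and 10.6 by another probe set), and Hoxa6 33.1 and 36.6. These were the strongest of 4 probe sets for Hoxa4 and of 2 each for Hoxb8 and Hoxa6. In sample 2 alone 21 of 28 cytokine receptor genes were above the control level. Measured cytokine receptor genes included Flt3 at 137 and 322, Tnfrsf1a at 62.8 and 83.5 (44.2 and 37.3 by another probe set), and Ifnar2 at 29.3 and 159. In the Wnt and Notch list Dvl1 had 103 and 99.8, Fzd4 79.5 and 101, and Ctnnb1, the gene of beta-catenin, 71.2 and 74.8. The thrombin receptor gene F2r, of the megakaryocyte list, had 332 and 209, Cd9 31.6 and 59.1, the von Willebrand factor gene Vwf 33.0 and 53.8, and F2rl2 16.1 and 20.3.

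**Figure D1:**
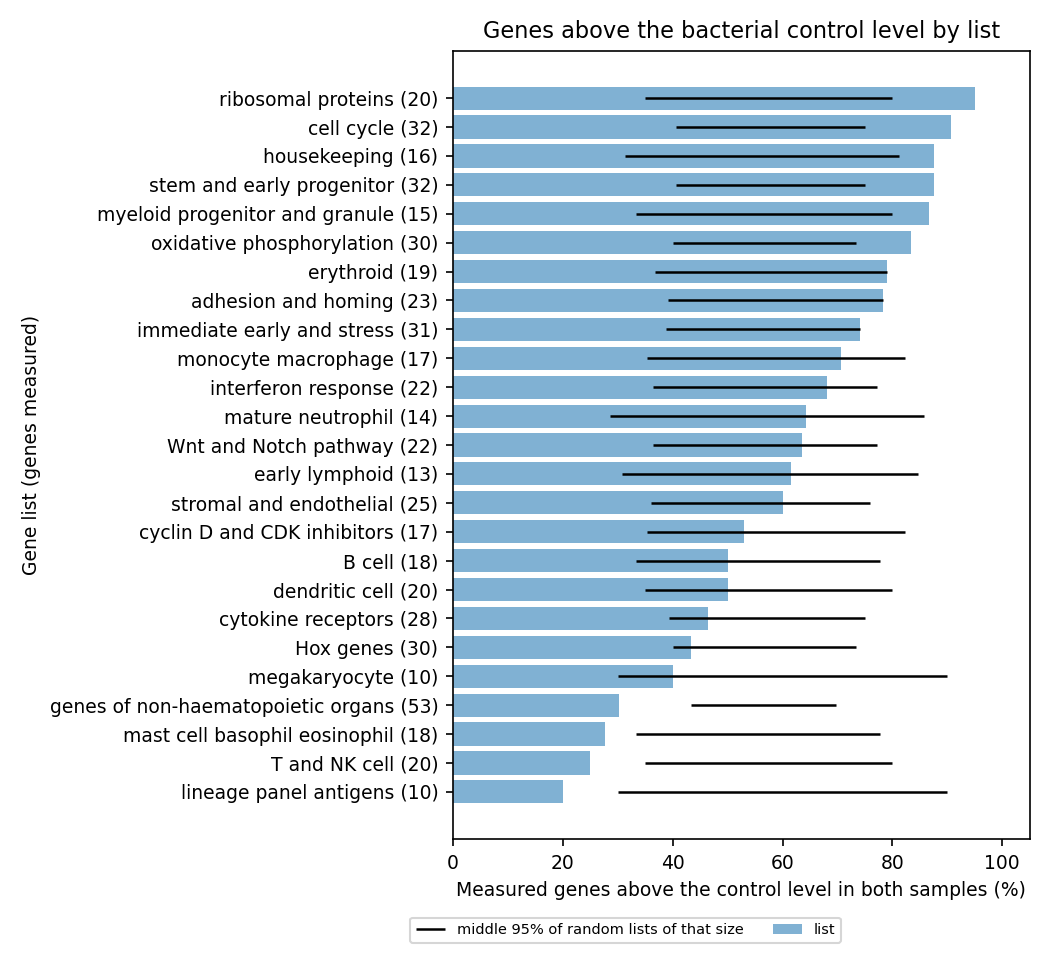
The bars give, for each gene list with at least 10 measured genes, the percentage of its measured genes with a signal above the bacterial control level in both samples, and the black lines give the middle 95% of random lists of the same size. Stem, cell cycle, ribosomal and oxidative phosphorylation genes lie above their lines, and lineage antigens, T and NK cell genes, mast cell genes and genes of other organs lie below.

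The control level was a permissive one. Of 53 measured genes of liver, pancreas, brain, muscle, germ cells and other organs, 16 were above it in both samples (30.2%), against 23 to 37 of random lists and 57.0% of all 8251 genes. Examples were the spermatid gene Tnp1 at 93.7 and 244, the lens crystallin gene Crybb2 at 88.3 and 77.1, the growth hormone gene Gh at 104 and 58.6 and the skin gene Lor at 66.0 and 13.4. In sample 2 alone 26 of the 53 were above it. A signal of this size therefore did not separate genes of other organs from genes of blood cells. A stricter level was the 90th percentile of the organ genes' own probe sets (41.6 in sample 1 and 27.9 in sample 2), chosen after seeing the data. Of the stem and early progenitor genes 14 of 32 remained above it, of the lineage antigens 0 of 10, and Kit did not. Of all 8251 genes 2059 remained, and no random lists were drawn at this level.

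The 2 samples agreed only in part. Across 12422 probe sets the log2 signals had a Pearson correlation of 0.85 and a Spearman correlation of 0.77, which are correlations across probe sets and not across independent replicates. The replicate SD was 0.44 on the log2 scale over all probe sets with the floor, which holds most values, and 0.95 without it, an alternative chosen after seeing the data. It was 0.58 over the 6118 probe sets above the control level in both samples. Of these, 1216 (19.9%) differed by 2-fold or more, 641 of them higher in sample 1 and 575 higher in sample 2. Which sample had more depended on the scaling, with 740 and 495 as deposited and 594 and 606 with median-centring. The median absolute difference was 1.35-fold. Among those with both signals at or above the floor, the 1056 probe sets with the strongest signals, a mean of 96.7 or more, had an SD of 0.77. Of these 31.9% were 2-fold or more apart, not counting strong probe sets that fell to the floor in 1 sample. The floor limits how far weak signals can differ, so their spread is not set beside this.

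Of 23 gene lists, 9 stood apart from random lists in the difference between the samples, where chance alone would give about 1.15 if genes varied independently. Of these, 5 were higher in sample 2 and 4 higher in sample 1. Immediate early and stress genes, many of them transcribed within minutes of a stimulus, had the largest median difference of the 23 and were higher in sample 2. Their median difference was 2.35 on the log2 scale, or 5.09-fold, with 17 of 23 genes higher in sample 2, 5 higher in sample 1 and 1 at the floor in both. Random lists of the same signal spanned -0.40 to 0.38, and the median was 1.54 with an offset of 32 on the log2 scale. Fos, a subunit of the transcription factor AP-1, had signals of 41.7 in sample 1 and 839 in sample 2, 20.1-fold apart. Egr1, a zinc finger factor of the same response, was 11.3-fold apart (36.4 and 410), the MAP kinase phosphatase gene Dusp1 9.51-fold (42.0 and 399), and the AP-1 gene Jund 6.68-fold (279 and 1862). The heat shock genes named by the rule went in different directions. Hspa8 was 1.65-fold higher in sample 1 (637 and 387), and Hsp90aa1 had 331 and 463. Of the listed genes only 3 had another probe set above the control level, with a median difference of 1.16.

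Genes of early lymphoid progenitors were higher in sample 2, and genes of myeloid progenitors and their granules were higher in sample 1. The early lymphoid median difference was 1.91, or 3.77-fold, with 7 of 8 genes higher in sample 2, against -0.81 to 0.71 for random lists. Dntt, which encodes the terminal transferase of antigen receptor rearrangement, had signals of 83.3 and 374, the leukocyte gene Lsp1 71.7 and 266, and the cytokine receptor gene Flt3, which the stem list also holds, 137 and 322. The myeloid progenitor and granule median was -1.32, or 2.49-fold higher in sample 1, with 10 of 13 genes in that direction, against -0.57 to 0.50 for random lists. Mpo, the myeloperoxidase of myeloid granules, had 1862 and 288, 6.47-fold apart (mean log2 signal 9.52 ± 1.90, SD, n = 2), and its other probe set had 67.5 and 23.9. Prtn3, a granule protease gene, had 459 and 342. Irf8, a factor of monocyte and dendritic cell development, went the other way, with 128 and 226. The sizes depended on the processing: the myeloid median was -0.67 with the mean over a gene's probe sets and -0.42 without a filter on low values, and the early lymphoid median was 1.22 and 1.23.

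Genes of the mature neutrophil list did not follow the myeloid progenitor genes. Of 9, 6 were higher in sample 2, 1 was higher in sample 1 and 2 were at the floor, with a median difference of 0.50 at the edge of the random lists (-0.56 to 0.49). The granule genes Camp (91.9 and 269) and Ngp (60.0 and 275) and the calprotectin gene S100a8 (301 and 459) were among them, and Padi4 was at least 3.72-fold higher in sample 2. This list stood apart under 2 of 6 alternatives. Monocyte and macrophage genes were at the opposite edge, with a median of -0.32 against -0.31 to 0.25, and stood apart under 0 of 6. Of these Apoe had 169 and 80.3, the endotoxin receptor gene Cd14 152 and 65.9, Ctss 74.4 and 100, and Lgals3 was at least 2.07-fold higher in sample 1.

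Cell cycle and respiratory chain genes were higher in sample 1. The median difference of 29 cell cycle genes was -0.59 (1.51-fold), with 21 higher in sample 1, against -0.42 to 0.33 for random lists. Pcna had 403 and 208, Cdc20 315 and 148, and Stmn1 380 and 293. For 25 oxidative phosphorylation genes it was -0.80 (1.74-fold), with 17 higher in sample 1, against -0.44 to 0.35. The ATP synthase gene Atp5a1 had 1337 and 737, the complex III gene Uqcrq 831 and 631, and Cox6a1 1755 and 1888. With an offset of 32 both medians were smaller, -0.34 for cell cycle and -0.47 for oxidative phosphorylation genes. Ribosomal protein genes had a median of -0.56, inside the random range of -0.62 to 0.42. The median was -0.22 with the deposited scaling and -0.081 with median-centring. Of 19 genes, 12 were higher in sample 1 and 6 higher in sample 2. Rps24 had 9585 and 5508, Rplp0 3633 and 2458 and Rpl41 3284 and 2133. Rps18, chosen after its values were seen, went the other way with 307 and 1850. The 14 other probe sets of cell cycle, oxidative phosphorylation and ribosomal genes above the control level had no common direction, with a median difference of 0.041. Those of Rps29, Atp5g1 and Atp5l were at the floor in both samples, and several belonged to Atp5d. Of the rest, one for Mcm3 (147 and 57.0) was higher in sample 1 and one for Rpl10a (242 and 444) higher in sample 2. The list of D-type cyclins and kinase inhibitors also holds Cdk4, Cdk6, Trp53, Gadd45g and genes of the Rb and Btg families. It was higher in sample 2, by a median of 0.74 over 9 genes against -0.64 to 0.58, with 2 of the 9 higher in sample 1. The antiproliferative gene Btg2 had 80.6 and 430 and the cyclin gene Ccnd3 79.6 and 264. The kinase gene Cdk4 went the other way, with 358 and 264. Without Btg2, which is also an immediate early gene, the median was 0.47 and the list no longer stood apart, and without a filter on low values it was 0.

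Stem and early progenitor genes had a small median difference, 0.29, or 1.22-fold higher in sample 2, with 16 of 28 in that direction, against -0.30 to 0.21. Without Egr1, which the immediate early list also holds, it was 0.22 and the list no longer stood apart. Both lists without immediate early genes were chosen after seeing the data.

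**Figure D2:**
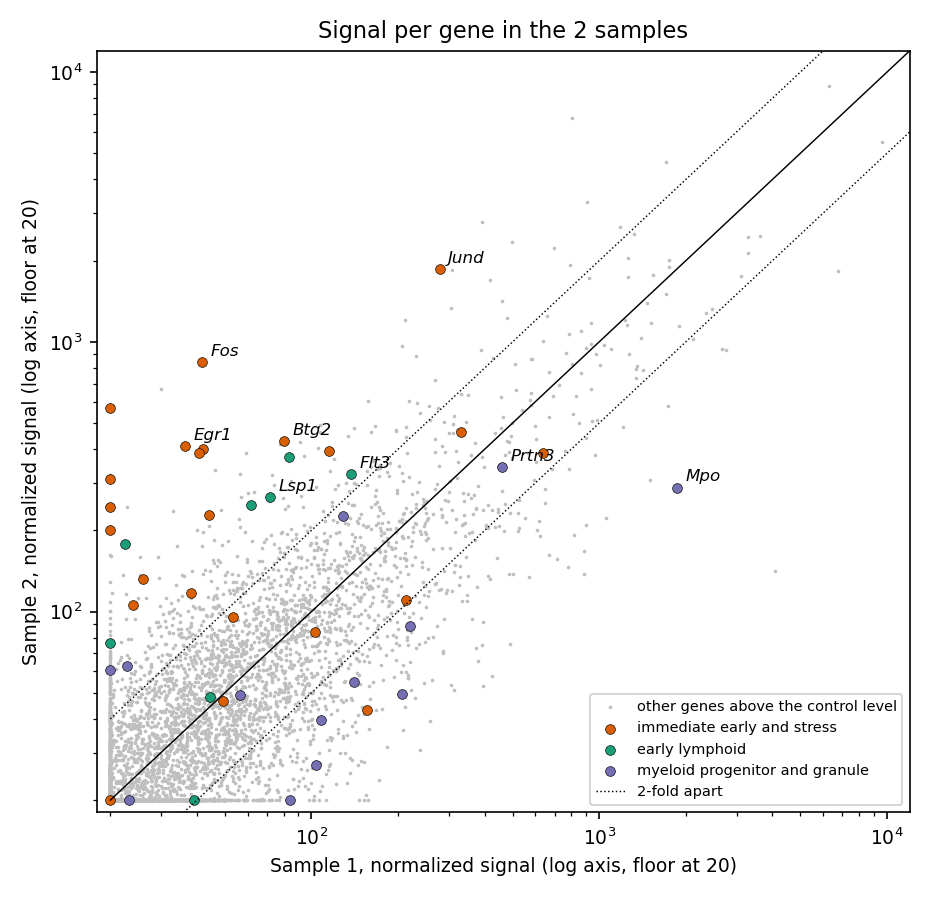
Each point is a gene above the control level in both samples, with its normalized signal in sample 1 on the horizontal and in sample 2 on the vertical axis, both logarithmic and with signals under 20 drawn at 20; coloured points are immediate early (orange), early lymphoid (green) and myeloid progenitor and granule genes (purple), the solid line marks equal signals and the dotted lines 2-fold differences. Fos, Egr1 and Jund lie far above the upper 2-fold line and Mpo lies below the lower one.

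The other 14 lists lay inside the range of random lists. Erythroid genes had a median of 0.24, but members went far in both directions. Hba-a1, the alpha globin gene, had 30.1 in sample 1 and 670 in sample 2, 22.3-fold apart, while Car1, the carbonic anhydrase of erythroid cells, had 488 and 75.9. The erythroid transcription factor gene Nfe2 had 213 and 442 and the transferrin receptor gene Tfrc 303 and 172. Housekeeping genes had a median of -0.023, which was 0.048 with median-centring and -0.34 with the mean over a gene's probe sets. Actb had 1466 and 1396 by the probe set used and 1209 and 79.7 by another, and Tpt1 had 901 and 951 and the elongation factor gene Eef1a1 6778 and 1837. Dendritic cell genes had a median of 0.28, with Cst3 at 551 and 222 (52.5 and 76.6 by another probe set), Tcf4 at 89.8 and 123 and the invariant chain gene Cd74 at 24.4 and 93.5. Interferon response genes had a median of 0.21, with Ly6e at 1710 and 4627 (30.3 and 21.5 by another probe set), B2m at 582 and 865 and H2-K1 at 435 and 459 (55.4 and 15.6, and 49.9 and 82.4, by others). The stromal and endothelial list had a median of 0. The endoglin gene Eng (419 and 1700) and Col4a1 (39.9 and 200) were higher in sample 2, Pecam1 (49.4 and 24.3) was higher in sample 1, and Col1a2 had 174 and 192. The medians were 0 for Hox genes, cytokine receptors, T and NK cell genes and genes of other organs, 0.017 for B cell genes, 0.035 for mast cell, basophil and eosinophil genes, -0.052 for the Wnt and Notch pathways and -0.15 for adhesion genes. With the deposited scaling the B cell and mast cell medians were -0.079 and -0.092, and the erythroid, dendritic cell, interferon response and Wnt and Notch medians were 0.15, 0.16, 0.076 and -0.12. Medians of exactly 0 came from genes at the floor. Without a floor they were 0.14 for Hox genes, 0.12 for cytokine receptors, 0.046 for T and NK cell genes, -0.29 for stromal and endothelial genes and -0.29 for genes of other organs, and the adhesion median was -0.40.

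**Figure D3:**
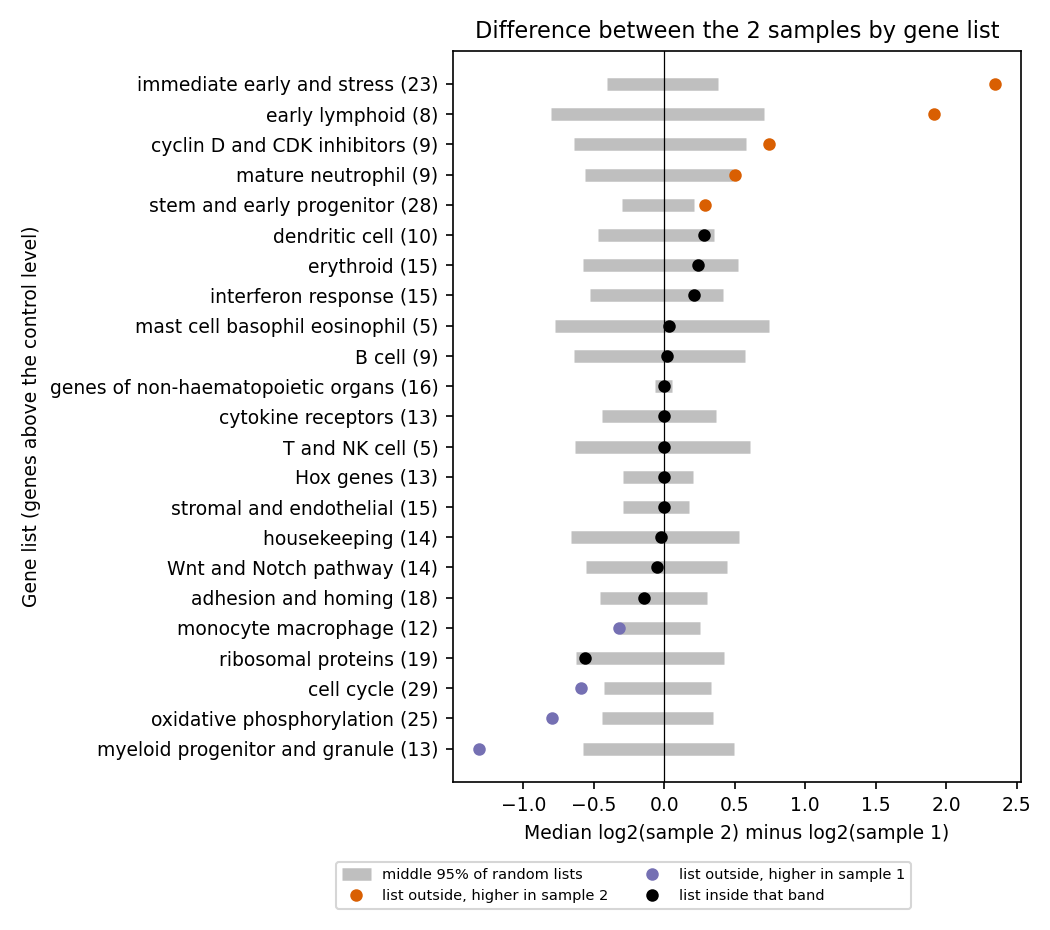
Points give the median log2 difference between sample 2 and sample 1 for each gene list with at least 5 genes above the control level, and grey bars the middle 95% of random lists of the same size and signal. Immediate early genes at 2.35 and early lymphoid genes at 1.91 lie farthest to the right, and myeloid progenitor and granule genes at -1.32 farthest to the left.

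Over all genes with both signals above the floor, the 5 most higher in sample 2 were Hba-a1, Fos, Egr1, Sertad1 (22.8 and 244) and Dusp1. In sample 1 the signals of Hba-a1 (30.1), Egr1 (36.4) and Sertad1 lay below the organ gene level of 41.6. Those of Fos (41.7) and Dusp1 (42.0) lay only just above it. The folds of all 5 therefore rest on weak signals in sample 1. The 5 most higher in sample 1 were the kinase gene Uhmk1 at 4097 and 141, 29.1-fold apart, the translation initiation factor gene Eif2b1 at 239 and 30.7, the complex III gene Uqcrb at 395 and 52.9, the vesicle GTPase gene Rab3a at 155 and 20.9, and Alas1, the first enzyme of haem synthesis, at 425 and 57.7. In sample 2 the signal of Rab3a lay below the organ gene level of 27.9 and that of Eif2b1 just above it. The fixed rule would also have ranked genes at the floor in 1 sample. Of these Klf6 was at least 28.3-fold, Gadd45b at least 15.5-fold and Atf3 at least 12.2-fold higher in sample 2. It would also have ranked the other Actb probe set, at 1209 in sample 1 and 79.7 in sample 2. No single gene has a replicate check beyond its 2 values.

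For the control transcripts Gapdh and Actb, the ratio of the signal at the 3' end to that at the 5' end was larger in sample 2 than in sample 1. For Gapdh the ratio of the 3' to the 5' probe set was 11.2 in sample 1 and 19.0 in sample 2 (mean log2 ratio 3.87 ± 0.53, SD, n = 2). For Actb it was 10.4 and 22.2 (3.92 ± 0.77, SD, n = 2). The ratio also carries the affinity of each probe set, so only the change between the samples can be read, 1.69-fold for Gapdh and 2.13-fold for Actb. The control probe sets for the bacterial genes BioB, BioC and BioD and the phage gene Cre, which are absent from mouse, also differed between the arrays. All 9 in the sense direction were higher in sample 2, by 1.13-fold to 4.12-fold with a median of 1.52-fold, and by a median of 2.28-fold as deposited. One of those for BioB had 87.8 and 362. These differences in the 3' ratio and in the control signals accompanied every difference between the samples given above.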

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

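All values in this part were picked out after the data were examined, because they lie outside the gene counts and above the highest bacterial control in both samples. The control probe set for the murine B2 repeat had a mean signal of 6722, with 7624 in sample 1 and 5819 in sample 2. The other B2 control had a mean of 372, and the B1 repeat control had a mean of 663. The probe sets for 18S ribosomal RNA had means of 264 at the 3' end, 367 in the middle and 74.2 at the 5' end. Of 15 antisense control probe sets 13 were above that level. The antisense control with the strongest mean signal, the 3' antisense set for the phage gene Cre, had 128 in sample 1 and 25.6 in sample 2, while the 3' sense set had 4133 and 6291. Of 1193 probe sets without a gene name 410 were above that level, and of 396 that name several genes 212 were.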

How the results depend on the processing

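The no-floor values, the deposited scaling for counts, the organ gene level and the lists without immediate early genes were added after seeing the data; the other alternatives were set before. For the differences between samples, the immediate early, early lymphoid, myeloid progenitor, cell cycle and oxidative phosphorylation lists stood apart in the same direction under all 6 alternatives, with medians of 1.54 to 2.37, 1.22 to 1.96, -1.38 to -0.42, -0.70 to -0.34 and -0.84 to -0.46. Other lists did not. The mature neutrophil median was 0.53 with median-centring, 0.26 with an offset of 32, 0.25 with the mean over probe sets and 0.50 without a floor, and no longer stood apart. It still did at 0.39 as deposited and 0.059 without a filter. The monocyte median was -0.39 as deposited, -0.32 with median-centring, -0.27 with the offset, 0 without a filter, -0.16 with the mean over probe sets and -0.67 without a floor, inside the random range each time. Without a filter the stem median was 0.088 and the cyclin median 0, and without immediate early genes they were 0.22 and 0.47, also inside. The ribosomal median stood apart only with the offset (-0.56), and was -0.22 as deposited, -0.081 with median-centring, -0.34 without a filter, -0.30 with the mean over probe sets and -0.56 without a floor. An offset of 32 lowered the probe sets 2-fold or more apart from 1216 to 491, and no floor gave 1529. They split into 740 higher in sample 1 and 495 higher in sample 2 as deposited, 594 and 606 with median-centring, 263 and 228 with the offset, 682 and 681 without a filter, and 855 and 674 without a floor. The Pearson correlation lay between 0.80 and 0.86 under all alternatives, but the replicate SD over all probe sets was 0.95 without a floor, against 0.44 with it. The cause was not tested, except that an offset shrinks the differences of weak signals by construction. No list that stood apart changed direction.

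Counts above the control level depend on that level. The probe sets above it in both samples were 9797 with the median bacterial control and 2531 with the organ gene level, which left 2059 genes of 4707. The deposited scaling cannot move these counts, as quantile normalization keeps the order within an array. With the median bacterial control the counts were 6 for lineage antigens, 22 for Hox, 23 for cytokine receptors, 18 for dendritic cell, 9 for megakaryocyte, 14 for mast cell, 17 for B cell, 16 for T and NK cell, 17 for cyclin and 39 for organ genes. With the organ gene level they were 0 for the sorting and for the lineage antigens, 14 for stem, 2 for Hox, 6 for cytokine receptors, 9 for adhesion, 6 for Wnt and Notch, 8 for myeloid progenitor, 4 for neutrophil, 4 for monocyte, 4 for dendritic cell, 9 for erythroid, 1 for megakaryocyte, 1 for mast cell, 3 for B cell, 5 for early lymphoid, 1 for T and NK cell, 4 for stromal, 18 for cell cycle, 4 for cyclin, 13 for immediate early, 8 for interferon and 5 for organ genes. With the array median they were 1 for lineage antigens, 9 for stromal and 10 for organ genes, and with the highest bacterial control 1 for lineage antigens. Where all probe sets of a gene had to pass, they were 1 for lineage antigens, 9 for Wnt and Notch, 5 for monocyte, 2 for megakaryocyte, 1 for mast cell, 5 for B cell, 5 for early lymphoid, 3 for T and NK cell, 9 for stromal and 8 for organ genes. In 1 sample alone, the counts ranged from 2 to 4 for lineage antigens, 15 to 21 for cytokine receptors, 7 to 10 for mast cell, 5 to 13 for T and NK cell and 21 to 26 for organ genes, the higher in sample 2 each time, whose control level was lower. Leaving out a sample leaves no difference to compute. No paired analysis was possible because the labels give only 1 group.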

Other observations

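The gene families and single genes of this and the next paragraph were chosen after their values were seen. Proteasome subunits were higher in sample 1: over 34 measured members above the control level the median log2 difference was -0.91, or 1.88-fold, against -0.36 to 0.30 for random lists, with 22 of 34 in that direction. Psmb4 had signals of 884 and 167, Psma6 393 and 75.2, and Psmc2 208 and 36.4. Subunits of the chaperonin that folds actin and tubulin had a median of -0.72 over 8 genes, 7 of them higher in sample 1, with Cct3 at 222 and 51.3. Their percentile was 1.34 with the floor and 3.45 without it. Mitochondrial ribosomal proteins had a median of -0.31 over 49 genes, with 32 higher in sample 1. Kruppel-like factors had a median of 0.81 over 8 genes, 6 of them higher in sample 2, and of these Klf6 was at least 28.3-fold higher there, while Klf1 had 215 and 80.5. Cathepsins (0.082 over 10 genes) and dual specificity phosphatases (0.19 over 6 genes) lay inside the random range.

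By the probe sets used, further immediate early genes lay at the floor in sample 1: Nr4a1 was at least 27.2-fold, Gadd45b at least 15.5-fold, Atf3 at least 12.2-fold and Jun at least 10.1-fold higher in sample 2. Another Gadd45b probe set had 37.4 and 83.2. The stress genes Hsph1 (157 and 43.1) and Hspa5 (213 and 110) were higher in sample 1. Among early lymphoid genes Notch1 had 22.5 and 178, Sox4 61.7 and 249 (40.6 and 27.9 by another probe set), and the recombinase gene Rag1 44.3 and 48.4, while Tcf3 was at least 1.95-fold higher in sample 1. Among granule and myeloid genes Elane had 220 and 88.4, Hp 206 and 49.4 and Lyz2 104 and 26.9, while Cebpd had 22.8 and 62.8 and Cebpb was at least 3.05-fold higher in sample 2. A probe set shared by Ly6c1 and Ly6c2 had 1157 and 363. Other globin probe sets were also higher in sample 2, a beta globin set shared by 4 genes at 65.5 and 209, and one shared by Hba-a1 and Hba-a2 at 78.8 and 590. Xist, the RNA of the inactive X chromosome, had 54.4 in sample 1 and 4.8 in sample 2, and the Y-linked genes Eif2s3y, Kdm5d and Uty had 14.3 and 23.0, 8.25 and 7.2, and 2.55 and 5.4. The labels give no sex for the animals.

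Of the tests in the next 3 paragraphs, those of mature granulocytes, of monocytes and of the scaling for parts of the last pattern, and the leaving out of single probe sets, were chosen after their values had been seen. The others were set out before their values were computed, for patterns found in these data. The design has 1 group, so no biological explanation was tested, and what differed between the 2 samples in animals, sorting or handling stays open. The granulocyte and monocyte lists were only set beside the direction such cells would give. The 3 scalings compared do not use the BioB, BioC, BioD and Cre controls, which were higher in sample 2 by a median of 1.52-fold, and a scaling to them was not run.

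Immediate early genes were higher in sample 2. Over all genes, the length of the gene on the genome (gene span) and the difference were correlated at only 0.061, a weak trend. The highest of 10000 lists matched on signal and gene span was 0.85, short of the median difference of 2.35. With so weak a trend, matched lists could hardly have reached it, so that comparison adds little to the correlation. Gene span is not the distance of a probe set from the 3' end, so the larger 3' ratios in sample 2 are not addressed by it. The choice among the 3 scalings made little difference, with medians of 2.23 to 2.37, above the random lists each time. That outcome could hardly have been another. Over all probe sets above the control level the scalings gave medians of only -0.18 to -0.046, and a common factor moves the random lists equally. Scaling in general is therefore not tested by it. Cross-hybridisation of single probe sets stays open, because only 3 other probe sets of these genes were above the control level, with a median of 1.16 at the upper edge of the random range (-0.96 to 1.16).

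Myeloid granule genes were higher in sample 1 and early lymphoid genes higher in sample 2. Mature granulocytes in sample 1 would carry the mature neutrophil genes with them, but that list had a median of 0.50, with 6 of 9 genes higher in sample 2. Among them was the abundant S100a8 (301 and 459), although its partner S100a9 had 56.8 and 55.4. The list stood apart under only 2 of 6 alternatives and its values had been seen beforehand, so it does not decide whether such cells were present. A lineage-negative gate is meant to remove them, but how well it did so is not known here. The gap of 3.23 between the medians of both lists lay above the highest of 10000 pairs of lists matched on signal and gene span, 1.93. Gene span and the difference were correlated at only 0.061 over all genes. Matched lists could therefore hardly reach the gap, and the comparison adds little. Gene span is also not the distance of a probe set from the 3' end. Monocytes or macrophages in sample 1 stay open, as their list, of which Apoe had 169 and 80.3, had a median of -0.32 and stood apart under 0 of 6 alternatives, although the same gate is meant to remove them. Cross-hybridisation of single probe sets is less clear: the other probe sets above the control level, 3 for each list, had a gap of 1.52, above the random range of -1.18 to 1.16, but leaving out 1 of them at a time gave 0.89 to 1.87, inside that range in 3 of 6 cases, so the bound set beforehand was too weak for so few probe sets and this stays open.

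Oxidative phosphorylation, ribosomal and cell cycle genes were together higher in sample 1. For oxidative phosphorylation and cell cycle genes the median nearest to 0 over 3 scalings was -0.66 (-0.46 for all 3 lists), below the random lists each time. The deposited and median-centred scalings differ by a common factor, which moves the random lists equally. The standing could therefore change only between quantile normalization and the others, and it did not. Scaling in general is not tested by this. The ribosomal genes had a median of -0.081 with median-centring. With quantile normalization that list already lay inside the random range of -0.62 to 0.42. The criterion for scaling was thus met beforehand, and nothing is concluded from it. For gene span, the joint median of -0.59 was below the 2.5th percentile of span-matched lists, -0.32. It was not below the lowest of them, -0.66, which was the bound set beforehand, so by that bound gene span stays open. Its correlation with the difference over all genes was only 0.061 here too. The 14 other probe sets of these genes had a median of 0.041, inside the random range of -0.25 to 0.23, with 4 lower in sample 2. Those of Rps29, Atp5g1 and Atp5l were at the floor in both samples and could show no direction, and several belonged to the single gene Atp5d. Differences of single probe sets therefore stay open as an explanation.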
